A study of Drosophila melanogaster with 2 samples.

How the data were processed

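Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos collected 0 to 4 h after egg laying. The labels describe 1 immunoprecipitated sample, precipitated with an antibody against CBP, and 1 chromatin input sample, each carrying the replicate number 1. Per the labels' protocols, untreated embryos were crosslinked with formaldehyde, the chromatin was sonicated, and an aliquot taken before precipitation served as the input. The growth protocol in the labels names iso1 or transgenic flies, without saying which of these gave the embryos used here.

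The file analysed is a list of enriched intervals (peaks) for the immunoprecipitated sample, in which each peak has a sequence name, a start, an end and a score. Per the file header, the peaks were called with MACS. Its version, its thresholds and whether duplicate reads were removed are not given in the sources used here. Per the submitters' processing notes, Bowtie and the genome build BDGP5 were used, and no Bowtie version or setting is given there. The design text of the series states in general that the chromatin input is the control, and whether this input entered this peak call is not stated for the list itself. The list belongs to 1 sample, and no second list was analysed here. The design text speaks of 2 replicates for such data sets, and whether reads were pooled before peaks were called is not given in the sources used here. Input reads and read coverage were not analysed here.

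The score is the authors' MACS score per deposited peak, and its scale is not stated in the file. It was used only to rank, filter and describe peaks within this list. The lowest listed score was 50.02, so the list holds only peaks above a score of about 50, and weaker binding cannot be described from it. Read depth is unknown, because the list holds no counts, and no interval that needs read counts is given. All intervals below cover the counting of peaks in this list only and say nothing of the spread between embryo collections.

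Positions are those of the list, on BDGP5, and are printed counting from 1 with the end included. The gene table at hand is of Release 6 and holds 17872 genes. None of the 6 heterochromatic and unplaced sequence names of the peak list occurs in it, and coordinates were not converted between releases. Under the plan fixed in advance, 3 of the 8 planned analyses (location relative to genes, lists of developmental genes near peaks, and motif content) were therefore not run. Peaks are named by position instead. The rule, fixed in the same way, names the 20 peaks with the highest score, the 5 widest peaks and the 5 clusters with the most peaks, with ties resolved by arm and start.

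Peak number, covered length, width and score were summarised over all listed peaks. A 95% interval of a median was taken from binomial order statistics. The association of width with score was measured with Spearman's rho across peaks, with a 95% interval from 1000 resamplings of peaks. For the 6 main arms (2L, 2R, 3L, 3R, 4 and X), the share of peaks was given with an exact Clopper-Pearson 95% interval. It was set beside the arm's share of the summed span, the span being the stretch from the first to the last peak, since chromosome lengths of this build were not at hand. Because neighbouring peaks are not independent, density was also compared between each large arm and the other large arms by resampling blocks of 1 Mb 1000 times. Peaks whose edges lay within 5 kb of each other were joined into clusters. The number of peaks in clusters was set beside 1000 random placements in which the peaks of each arm kept their widths, did not overlap and stayed within the span. The percentile among placements describes this list and is not a p-value for a biological difference.

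The clustering procedure was tested on simulated data of 1326 peaks. Of 40 lists placed at random, 0 lay above the 97.5th percentile of their own random placements, and of 20 lists with 100 planted neighbour pairs, 20 did. Both kinds of list started from the same rule of placement as the reference. They therefore check the calculation only, and cover neither an uneven background density nor splitting of regions by the caller. The other settings tried, fixed before the data were examined, were a minimum score equal to the median, cluster distances of 2 kb and 10 kb, all listed sequences, the share of covered bases in place of peak number, and the exclusion of the 5% widest peaks. Calculations were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9.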

Results

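Genome-wide binding of CBP was mapped in embryos collected over the first 4 h of development. CBP (CREB-binding protein, the product of nejire in Drosophila) is a transcriptional co-activator and histone acetyltransferase that is recruited to enhancers and promoters by sequence-specific factors. The collection spans the cleavage divisions, the activation of the zygotic genome, cellularization and gastrulation. The data comprised 1 ChIP sample, for which a peak list was analysed, and 1 input sample. Since there was 1 ChIP sample, no value has a replicate error, and read depth is unknown.

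The first question was where, and over how much sequence, CBP was enriched in these embryos. The list held 1347 peaks covering 921884 bp on BDGP5. Of these, 1326 lay on the main arms, where they covered 913296 bp, and 21 lay on heterochromatic or unplaced sequences. The median peak was 622 bp wide (95% interval 605 to 637), with quartiles of 457.5 and 831 bp and extremes of 213 and 2779 bp. Peaks wider than 1000 bp numbered 178, or 13.2% of the list. The authors' score had a median of 68.22 and ranged from 50.02 to 617.96. Scores between 50 and 60 were held by 448 peaks (33.3%) and scores between 60 and 70 by 270 peaks, so the list was most crowded next to its lower limit. Scores of at least 100 were reached by 288 peaks (21.4%), and 18 peaks reached 300.

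The highest-scoring peaks were spread over the large arms and the unplaced sequences. Of the 20 highest-scoring peaks of the whole list, 15 lay on the main arms, 5 each on 2R and 3L, 3 on 3R and 1 each on 2L and X. The highest of them spanned 2L from 8675339 to 8676012, with a score of 546.27 over 674 bp. The peak on 2R from 16935065 to 16937007 and that on 3L from 8099655 to 8100717 shared a score of 387.42, with widths of 1943 and 1063 bp. Further peaks on 3L lay from 6177625 to 6178330 (score 384.34), from 13371164 to 13372238 (score 359.08), from 15501841 to 15503018 (score 333.13) and from 21059267 to 21060243 (score 295.62). On 2R, the list gave scores of 375.19 from 15548985 to 15550001, 338.2 from 2519666 to 2520774, 330.16 from 9456984 to 9458790 and 324.82 from 5964492 to 5965227. The 3 peaks on 3R spanned 2689374 to 2690388 (score 345.18), 24684704 to 24685622 (score 326) and 26737820 to 26738973 (score 299.87). The X was represented by the peak from 9578021 to 9579447, with a score of 361.32 over 1427 bp. These 15 peaks were 674 to 1943 bp wide, with a median of 1063 bp.

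The other 5 of the 20 highest-scoring peaks lay on the unplaced sequences U and Uextra, including 4 of the 5 highest scores of the list. On Uextra, the peak from 19603805 to 19604129 scored 617.96, that from 7039304 to 7039806 scored 604.5, that from 17025986 to 17026321 scored 558.52 and that from 2684428 to 2684902 scored 420.97. On U, the peak from 5301680 to 5301961 scored 348.92. These 5 peaks were 282 to 503 bp wide, below the width of each of the 15 arm peaks among the 20.

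**Figure D1:**
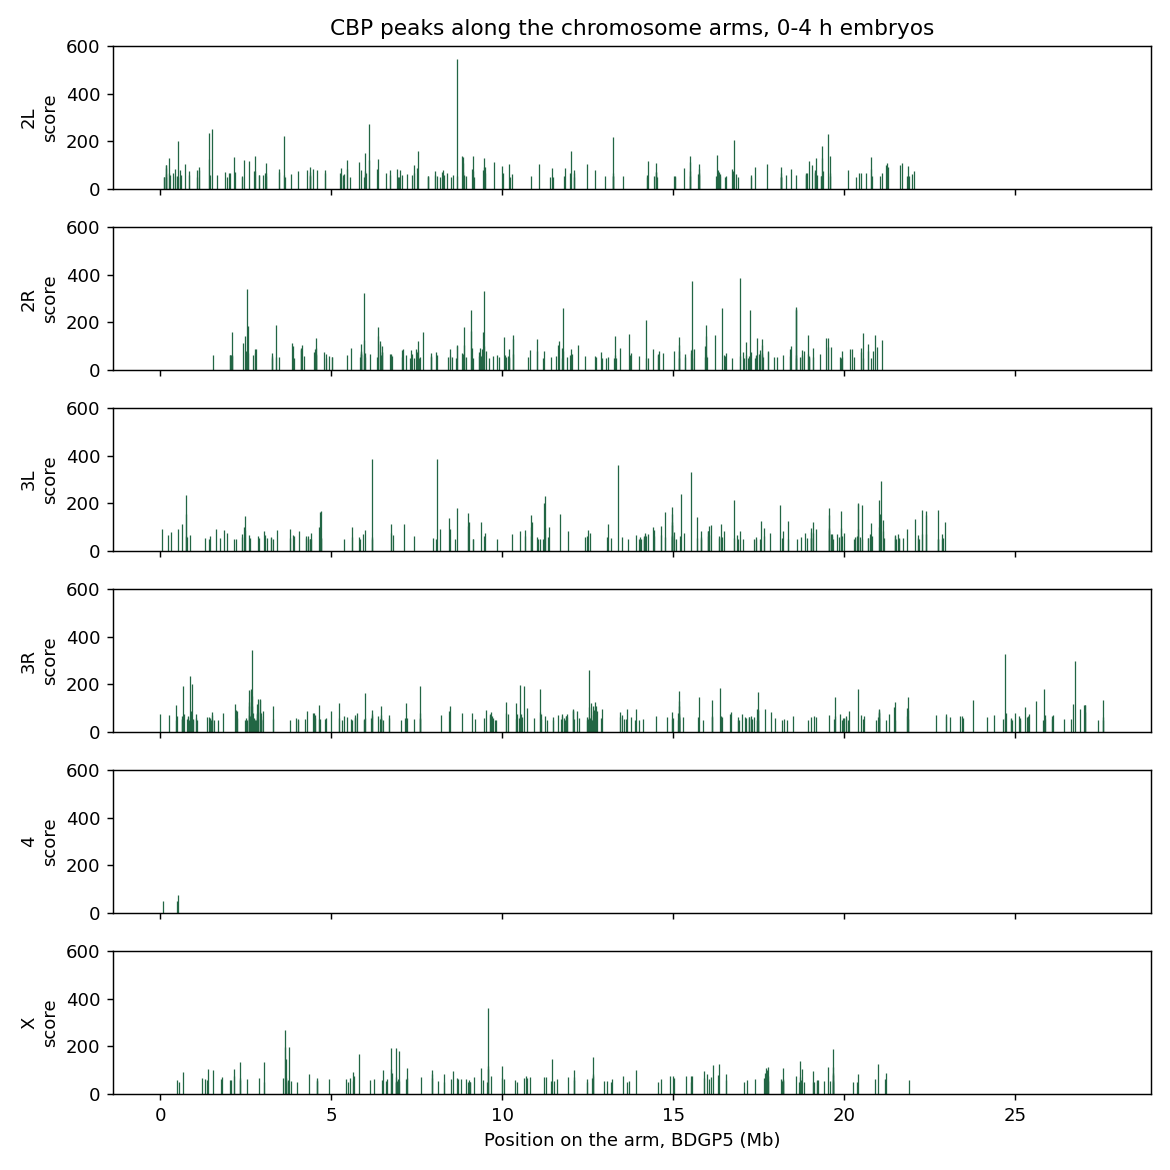
Position of each CBP peak on the main chromosome arms (horizontal axis, Mb on BDGP5) and the authors' MACS score (vertical axis, no unit), 1 line per peak. The peak on 2L at 8675339 to 8676012 reaches 546.27, and most other peaks lie below 100.

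Wider peaks tended to score higher. Across the 1347 peaks, width and score were associated with a Spearman's rho of 0.471 (95% interval 0.427 to 0.510), and peaks are not independent replicates. When the arm peaks were ordered by score, the 332 lowest had a median width of 495 bp (95% interval 466 to 521) and the 331 highest a median of 845 bp (95% interval 805 to 877). The 5 widest peaks were not among the 20 with the highest score. The 5 widest spanned 3R from 23755730 to 23758508 (2779 bp), 2R from 11018021 to 11020515 (2495 bp), 2R from 10060243 to 10062692 (2450 bp), 2L from 2752354 to 2754693 (2340 bp) and 2R from 4542136 to 4544415 (2280 bp). Their scores were 135.3, 132.29, 139.06, 138.08 and 136.54, which placed them between rank 130 and rank 155 of the 1347 peaks.

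**Figure D2:**
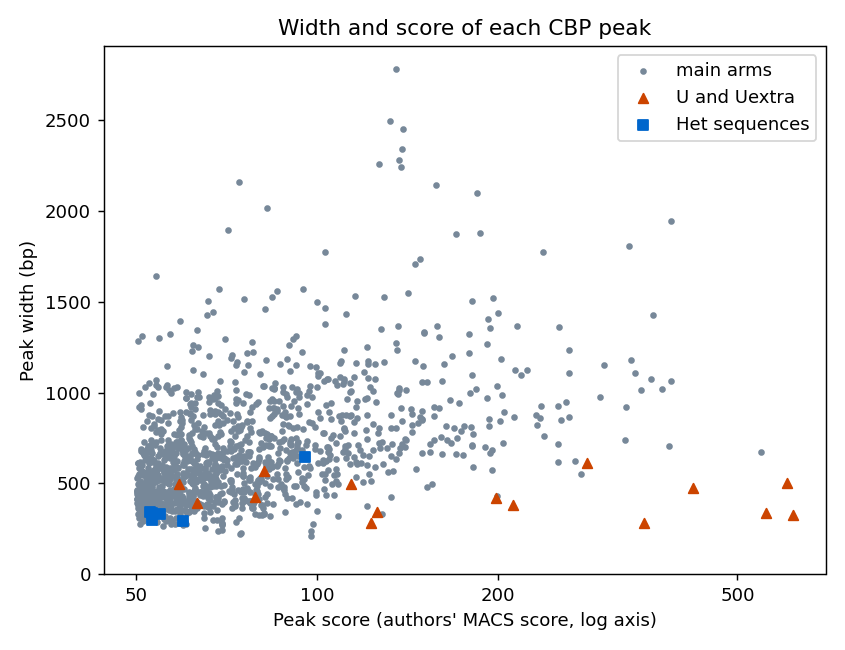
Width of each peak in bp (vertical axis) against the authors' MACS score (horizontal log axis, no unit), with grey points for the main arms, triangles for U and Uextra and squares for the heterochromatic (Het) sequences. Peaks on U and Uextra reach 617.96 in score but stay at or below 614 bp in width.

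The distribution over the arms was uneven, with fewer peaks on the X than its span would give. The X held 187 of the 1326 arm peaks, a share of 14.1% (exact binomial 95% interval 12.3 to 16.1), while its span from 482816 to 21883988 made up 18.8% of the summed span. Its density was 8.74 peaks per Mb against 12.4 over the large autosomal arms, a ratio of 0.707 (95% interval from 1 Mb blocks 0.578 to 0.858). Neither read depth on the X nor the sex of the embryos was known. Arm 2R held 274 peaks, or 20.7% (18.5 to 22.9), on 17.2% of the span, and its density of 14.0 peaks per Mb was 1.25 times that of the other large arms (1.05 to 1.49). Those arms include the X, and against 2L, 3L and 3R alone the ratio was 1.18, with an interval of 0.977 to 1.42 that includes 1. The span of 2R began at its first peak, at 1541152, and counting the sequence before it would lower the density of 2R. Arm 3R held the most peaks, 361 or 27.2% (24.8 to 29.7), on 24.2% of the span. The ratio for 3R was 1.17, with a block interval of 0.915 to 1.49 that includes 1, so an excess on 3R does not hold up once neighbouring peaks are allowed for. Arms 2L (246 peaks, 18.6%) and 3L (255 peaks, 19.2%) had shares whose intervals include their shares of the span, 19.3% and 20.1%. Chromosome 4 held 3 peaks between 79502 and 522823. The median peak width was 555 bp (520 to 585) on the X, 673.5 bp (640 to 712) on 2R and 643.5 bp (616 to 671) on 2L. It was 631 bp (599 to 667) on 3R, 609 bp (559 to 653) on 3L and 410 bp over the 3 peaks of chromosome 4. The interval of the X lies below those of 2L, 2R and 3R and overlaps that of 3L. The median scores of X and 2L, 66.79 (64.42 to 71.55) and 68.745 (66.23 to 73.84), had overlapping intervals.

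**Figure D3:**
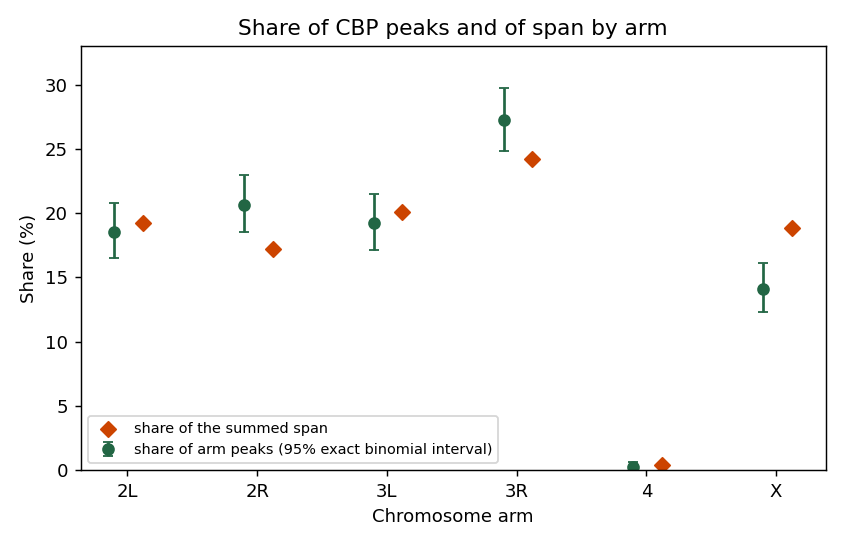
Share in percent (vertical axis) of the 1326 arm peaks on each chromosome arm (horizontal axis), as circles with exact binomial 95% intervals, beside the arm's share of the summed span as diamonds. The X holds 14.1% of the peaks on 18.8% of the span.

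CBP peaks lay close together more often than placements at random. Of the 1326 arm peaks, 493 (37.2%) had a neighbour within 5 kb and formed 201 clusters. Random placement within the same arms gave 150 ± 15.8 peaks in clusters (mean and SD over 1000 placements) and at most 196, so the observed number was 3.29 times the random mean and above all 1000 placements. Most clusters were pairs: 140 had 2 peaks, 43 had 3, 10 had 4, 5 had 5, 2 had 6 and 1 had 7. The share of peaks in clusters was 41.2% (35.4 to 47.3) on 2R, 38.2% (32.1 to 44.6) on 2L, 37.6% (31.7 to 43.9) on 3L, 35.7% (30.8 to 40.9) on 3R and 32.6% (26.0 to 39.8) on X, and these exact binomial 95% intervals overlap.

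The cluster with the most peaks spanned 15448 bp of 3L from 14955802 to 14971249 and held 7 peaks with scores of 58.02 to 186.32, which together covered 6615 bp. On 3R, a cluster from 668572 to 678918 held 6 peaks with scores of 54.19 to 193.5, and a cluster from 15164680 to 15176662 held 6 peaks with scores of 64.8 to 174.57. The unplaced sequence U carried 6 of its 7 peaks in a cluster from 5288388 to 5301961, with scores of 78.72 to 348.92. As U is unplaced and may consist of short pieces and repeated copies, distance along it may not be distance on a chromosome. On 2L, a cluster from 155443 to 167136 held 5 peaks with scores of 51.03 to 103.34, and it was listed ahead of other clusters of 5 by its position. The excess depended on the distance and on the reference placement: it was 5.46 times the random mean at 2 kb, and 1.85 times the mean of placements that moved each peak by up to 50 kb.

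**Figure D4:**
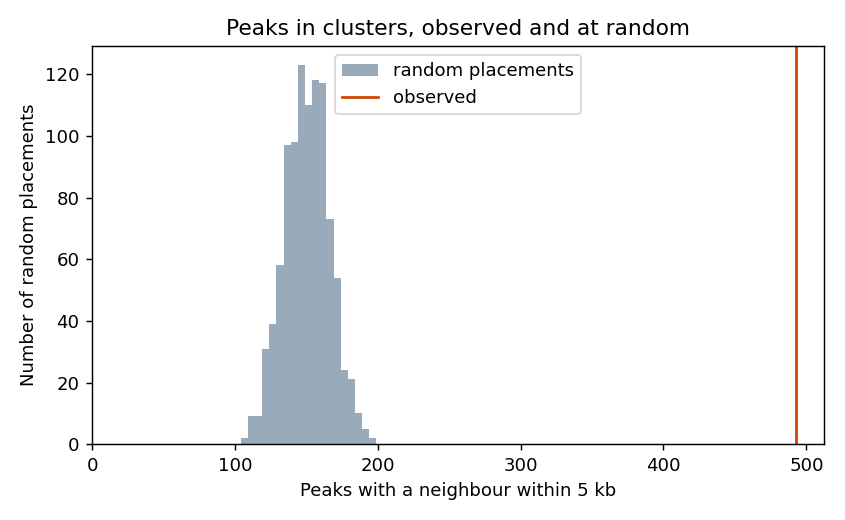
Number of random placements (vertical axis, histogram over 1000 placements of the arm peaks) by the number of peaks that have a neighbour within 5 kb (horizontal axis). The vertical line marks the 493 peaks observed, and the highest random placement gave 196.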

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

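The tests on the unplaced sequences and on the X in this part were chosen after the results were seen, and those on the clusters were written down before their outcome was known.

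Peaks on sequences that the comparison of arms does not use were marked for a closer look because signal was present there. The list holds 21 such peaks, and no expected number is known for these sequences. The 6 peaks on heterochromatic (Het) sequences had a median score of 53.87 and none exceeded 95.54, while the 15 peaks on U and Uextra had a median of 198.03, against 68.095 on the main arms. An explanation by short pieces and repeated copies may apply, and the widths on U and Uextra lay at a median percentile of 2 among the 50 arm peaks nearest in score, with 13 of 15 under percentile 25. The low-scoring Het peaks were narrow as well, at a median percentile of 7 with 5 of 6 under percentile 25, so narrowness does not go with high score alone and leaves this explanation open. No biological explanation was tested, because the design has no second condition.

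Peaks were sparser on the X than on the large autosomal arms, by a ratio of 0.707. Resampled 1 Mb blocks gave an upper bound of 0.858 for this ratio, which argues against uneven density sampled by chance. However, the X was singled out as the sparsest large arm, and the interval makes no allowance for that choice. A lower read depth on the X is a candidate explanation, because an embryo collection of mixed sex carries fewer X copies than autosome copies, although the labels give no sex. If scores fell in proportion to a depth of 0.75, X density at the listed threshold should equal autosomal density at a threshold higher by that factor, but it was 1.32 times as high (95% interval 1.06 to 1.63), so this scaling predicts a larger deficit than was seen. The scaling is assumed rather than measured, so depth stays open, as does a true difference in binding between X and autosomes.

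Peaks lay within 5 kb of each other more often than random placement gave, 3.29 times the random mean. Splitting of single regions by the peak caller at gaps of up to 500 bp does not account for all of it. Of the 1320 gaps between neighbouring arm peaks, 292 were at most 5 kb, and 100 of these were at most 500 bp. After the peaks across these 100 gaps were joined, 334 peaks were in clusters, 2.59 times the random mean and above all 1000 placements. The excess fell from 3.29 to 2.59, so such splitting may account for part of it, and splitting at wider gaps was not tested. Broad regional density alone is also argued against, since the number was 1.85 times the mean of placements within 50 kb of each peak. The highest of these 1000 placements gave 319 against 493. They used the list before joining, so splitting and regional density acting together were not tested. Both acting together, splitting at wider gaps and density that varies over distances shorter than 50 kb all remain open. A further hypothesis, not tested here, is that CBP occupies several neighbouring regulatory elements of the same loci. It may be tested with gene annotation of BDGP5, not used here.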

How the results depend on the processing

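No paired analysis was possible because each group has 1 sample, which leaves no second pair, and the input reads were not analysed here. With 1 sample per group, no replicate could be left out. Analyses of location relative to genes, of gene lists and of motifs, with the settings listed for them, were not run. Of 37 alternative values, 27 stayed within 1.5 times the main count, within the main 95% interval or kept an interval that includes a ratio of 1. Of those, 18 were the shares of the 6 arms, with X between 12.5% and 13.9% against 14.1%. Taking all listed sequences or the main arms alone changed the list by only 21 peaks, so those values could hardly move. The numbers of clustered peaks at 2 kb, at 10 kb and after joining were among the 27, although their excess over the random mean moved. Keeping only peaks with a score at or above the median of 68.22 left 674 peaks covering 539743 bp, with a median width of 728 bp in place of 622 bp and 191 peaks in clusters. The smaller counts follow from the filter itself. The excess of clustered peaks over the random mean, 3.29 at 5 kb, was 4.90 under that filter, 5.46 at 2 kb, 2.20 at 10 kb, 2.59 after joining peaks within 500 bp and 1.85 with placement within 50 kb of each peak. The observed number of clustered peaks was above all 1000 placements in each of these settings. The density ratio of 2R, 1.25 against the other large arms, was 1.18 against the large autosomal arms alone, with an interval that includes 1. Added after seeing the data were the joining and the placement within 50 kb (before their outcome was known), the restriction to the main arms (1326 peaks, 913296 bp) and the block comparison of densities with its restriction to autosomal arms. Without the 5% widest peaks, rho of width and score was 0.443 in place of 0.471. Read depth is unknown, and 448 of 1347 peaks scored under 60, close to the lower end of the list at 50.02, so that the number of peaks rests on the authors' threshold.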

Other observations

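The observations in this part were all chosen after the results were seen. In fixed windows of 100 kb along the arms, 11 windows held at least 7 CBP peaks, and 8 of them lay on 3R. That arm held 27.2% of the arm peaks on 24.2% of the span, and its density ratio of 1.17 had an interval that includes 1. Some of the 8 windows adjoin each other, so they are not independent. The fullest, from 15100001 to 15200000 on 3R, held 10 peaks, and the windows from 600001 and from 2600001 on 3R held 9 each. On 3R the windows from 2900001 to 3000000 and from 12500001 to 12600000 held 8 each. The windows from 4500001 to 4600000 and from 9300001 to 9400000 on 2R and from 14900001 to 15000000 on 3L held 7 each, as did those from 2700001, 11800001 and 17400001 on 3R. In 1000 random placements, the fullest window on the arms held 6.08 peaks on average and 9 at most. These placements follow the same rule as those of the clustering comparison. The fullest window also holds the cluster already named on 3R from 15164680 to 15176662, so full windows are not a finding separate from the clustering. Of the 1164 windows, 48 held 5 or more peaks and 524 (45.0%) held none. Windows were counted from the start of each arm, so empty ones before its first peak are included. No random value is given for empty windows or for gaps, so neither can be called unusual. The longest gap between neighbouring peaks on an arm was 0.823 Mb, from 21868720 to 22691934 on 3R, followed by 0.720 Mb from 13513719 to 14233334 on 2L. Stretches before the first and after the last peak of an arm were not counted as gaps. On 2R the first peak starts at 1541152, so the stretch before it is longer than these gaps.

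The highest-scoring peaks were more often in clusters than the others. Of the 331 highest-scoring arm peaks, with scores from 92.13, 165 had a neighbour within 5 kb (49.8%, exact binomial 95% interval 44.3 to 55.4), against 107 of the 332 lowest-scoring ones (32.2%, 27.2 to 37.5). The share was 31.0% (26.1 to 36.3) and 35.6% (30.5 to 41.1) in the groups of 332 and 331 peaks between them, whose intervals overlap that of the lowest group. Peaks in clusters had a median score of 73.53 (69.72 to 77.23) and a median width of 680 bp (657 to 703), and the 833 peaks alone had medians of 65.98 (64.73 to 67.70) and 582 bp (556 to 605). All these intervals treat peaks as independent, although the peaks of a cluster share their membership, so the intervals may be too narrow. The comparison was not repeated after joining close peaks, so a contribution from splitting of single regions was not tested. For the scores of adjacent peaks within 5 kb, rho was 0.0988 over 292 pairs. This lay near the upper end of the range of -0.117 to 0.106 that held 95% of 1000 shufflings of scores within arms. A weak association was thus neither shown nor excluded. For the 1028 pairs of adjacent peaks further apart, rho was 0.0127.

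One peak on 3R is listed from position -61 to 1087, with a score of 76.77, so its start lies before the first base of the arm.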
